A study of Mus musculus with 2 samples.

How the data were processed

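H3K9me3, trimethylation of lysine 9 of histone H3 and a mark of silent heterochromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in kidney tissue of mouse embryos (strain B6NCrl, age 16.5 days, pools of both sexes, per the labels). The labels give 1 group with 2 biological replicates. Replicate 1 had 1 technical replicate and replicate 2 had 2 technical replicates from a pool of 41 embryos. The number of embryos behind replicate 1 is not given in the sources used here.

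The deposited files used here were 4 peak lists on mm10 (GRCm38), per the labels. The authors called 1 list on each replicate and 1 on both replicates pooled, and derived the replicated list from these 3, per the deposited readme text. Both single lists and the pooled list also derived from the same 2 further files, whose roles are not stated there. A control experiment is named in the labels as a possible control. The aligner, the peak caller and the filters are not given in the sources used here. For each peak the authors gave a fold, read as a ratio of enrichment over background from the narrowPeak format, and −log10 of a p-value and of a q-value. The lowest −log10 p in any list was 2.01. These values belong to the peaks as the authors called them and were used to rank or filter peaks within a list. Between the replicate lists, the folds of shared peaks were compared only by rank and, for X against autosomes, as a ratio, and a factor common to a whole list changes neither. The lists hold no read counts, so the depth is unknown and no counting interval is given.

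From the peak lists, overlaps and coverage were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Genes came from the GENCODE basic mouse annotation of GRCm38, and sequence from the GRCm38 RefSeq assembly. All peaks lay within the chromosome ends of that assembly. Tests used the 21 assembled chromosomes, X and Y included. Peaks on other scaffolds were left out of these tests, except in the comparison of small-p peaks with assembly gaps, which counted them.

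Chance expectation came from circular shifts. All peaks of a chromosome were moved together by a random distance, which keeps their spacing, and the observed value was compared with 10000 such shifts in a two-sided permutation test. The smallest p these shifts can give is 0.0001. Such a p measures the placement of peaks along the genome, not the spread between replicates, and shifts do not account for where reads can be mapped uniquely. The alternatives used 2000 shifts, except 300 for replicate overlap, 500 for compartments by any overlap, 300 for random placement and 200 for sequence. Main values of sequence composition used 1000 shifts, with a smallest p of 0.001. Intervals of shifts and of bootstrap draws span 95%. The Benjamini-Hochberg adjustment ran over the 26 gene lists, and over the 4 compartments, at a threshold of 0.05.

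Overlap of replicates was counted from 1 bp. A gene counted as marked when its body held a replicated peak. Compartments were assigned by peak midpoint, with a promoter taken as 1 kb on both sides of a transcript start. For the zinc finger genes, the last exon of the longest transcript was compared with the promoter, 2 kb on both sides of the 5′ end. Domains were replicated peaks merged within 10 kb. Values for each replicate list are given with their mean and SD over n = 2. The gene lists, the tests, the alternatives below and the rule for named genes were fixed before the data were examined. That rule took the 10 protein-coding genes with the most bases covered, up to 3 members of each list with the most bases covered, the 10 replicated peaks with the highest fold, and the 10 domains with the most bases covered.

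The shift test was tested on simulated data for the 424 zinc finger genes, in 100 simulations with 200 shifts each. With the replicated peaks of each chromosome moved together by a random distance, 4 of 100 simulations passed the threshold. The test makes the same move, so a rate near the threshold follows by construction. It does not show how the test behaves where mapping or sequence differs between regions. With a peak also added to 40 of the genes, drawn at random, 79 of 100 passed, and with 80 genes 100 of 100 passed.

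The alternatives were the pooled list, the list of each replicate alone, peaks with −log10 q of 1.3 or more, and peaks at or above the median fold. Others were gene bodies extended by 5 kb, promoters alone, at least 500 bp covered, 10000 random gene lists matched on length, random placement of peaks outside gaps, compartments by any overlap, the last 5 kb of the gene body, percent of bases covered, and merging distances of 5 and 25 kb. Signal tracks were not used here.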

Results

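H3K9me3 peaks were mapped in the kidney of mouse embryos at 16.5 days, in 1 group of 2 biological replicates. The list of replicate 1 held 59091 peaks over 16.7 Mb with a median fold of 3.12, and that of replicate 2 held 69718 peaks over 21.6 Mb with a median fold of 3.38. The pooled list held 58874 peaks. The replicated list held 29967 of these (50.9%), unchanged, over 13.7 Mb, with a median width of 369 bp and a median fold of 3.71. Of the 29722 replicated peaks on assembled chromosomes, 77.7% overlapped peaks of both single lists and 81 overlapped neither, so the list is wider than the overlap of both. Replicated peaks covered 0.507% of the bases outside gaps. The share of peaks with −log10 q of 1.3 or more was 53.2% in replicate 1, 73.2% in replicate 2 and 97.9% in the replicated list. The depth of the libraries is unknown, since the lists hold no read counts. All fold values are the authors' own values per peak.

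The first question was how far the replicates marked the same places. Of the replicate 1 peaks on assembled chromosomes, 25527 of 58741 (43.5%) overlapped a replicate 2 peak, and 24920 of 69362 replicate 2 peaks (35.9%) overlapped a replicate 1 peak. Shifted lists gave 1.63% and 1.39%, with permutation p = 0.0001 in both directions, the smallest the shifts can give. Peaks of high fold were shared more often. In the quintile of highest fold 72.0% of replicate 1 and 63.4% of replicate 2 peaks were shared, against 30.5% and 22.4% in the quintile of lowest fold. The lists shared 6.60 Mb, a Jaccard index of 0.211 over bases. Across 23103 replicated peaks found in both lists, the fold in replicate 1 and in replicate 2 had a Spearman correlation of 0.301. This correlation is across peaks, which are not independent replicates. Both lists derived from the same 2 further files, so part of the overlap over chance may be shared through them.

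**Figure D1:**
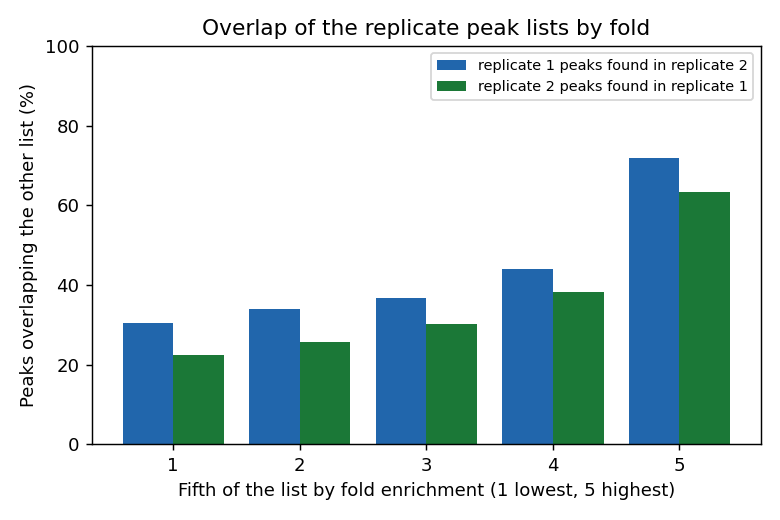
Percent of peaks of each replicate list that overlapped the other list by at least 1 bp (y axis), by quintile of the authors' fold within the list (x axis), replicate 1 in blue and replicate 2 in green. The overlap rose from 30.5% to 72.0% in replicate 1 and from 22.4% to 63.4% in replicate 2.

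The next question was which genes carried the mark. Among 26 gene lists, 4 held peaks more often than shifted peaks did: clustered protocadherins, imprinted genes, germline genes and zinc finger genes. The raw permutation p was 0.0002 for germline genes and 0.0001 for the other 3, the smallest the shifts can give. No list held peaks less often than chance at an adjusted p under the threshold. Over all protein-coding genes, 4514 of 21938 (20.6%) held a replicated peak, against 21.7% by chance (permutation p = 0.0044).

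The clustered protocadherins, adhesion genes of neurons that lie in 3 tandem clusters on chromosome 18, held peaks in 55 of 57 members (96.5%, against 39.8% by chance, adjusted permutation p = 0.00087). The replicate lists gave 100% and 98.3% (99.1% ± 1.24, SD, n = 2). All 22 beta and all 21 gamma members and 12 of 14 alpha members held a peak. The exceptions, named after their values were seen, were Pcdhac1 and Pcdhac2. Of the gamma members, Pcdhgc3, Pcdhgc4 and Pcdhgc5, also named after their values were seen, held only the same single peak (37819718 to 37820996). Its fold was 2.29, and it lay past the end of the largest domain at 37778133. The gene bodies are nested and form 23 separate loci, so members are not independent. Pcdhga1 (chromosome 18, 37661793 to 37841873, mm10) had 90.1 kb of its 180081 bp body covered (50%), Pcdhga2 86.7 kb and Pcdhga3 82.5 kb, with a highest fold of 12.8 for each. These genes, with Pcdhgb1, Pcdhga4, Pcdhgb2, Pcdhga5 and the transcripts Gm42416, Gm37013 and Gm37388 that run over the same region, were the 10 protein-coding genes with the most bases covered. Chance rose to 51.7% in the pooled list and to 54.7% and 55.1% without replicate 1 and without replicate 2. The list was no longer past the threshold in the list of replicate 2 alone (adjusted permutation p = 0.11), of replicate 1 alone (0.058) or in the pooled list (0.16). In each of these lists a shift that leaves every member without a peak lies further from the chance mean than the observed share does. The two-sided test counts such shifts there, but not for the replicated list. Their number was not counted, so how far they account for the lost call is open.

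**Figure D2:**
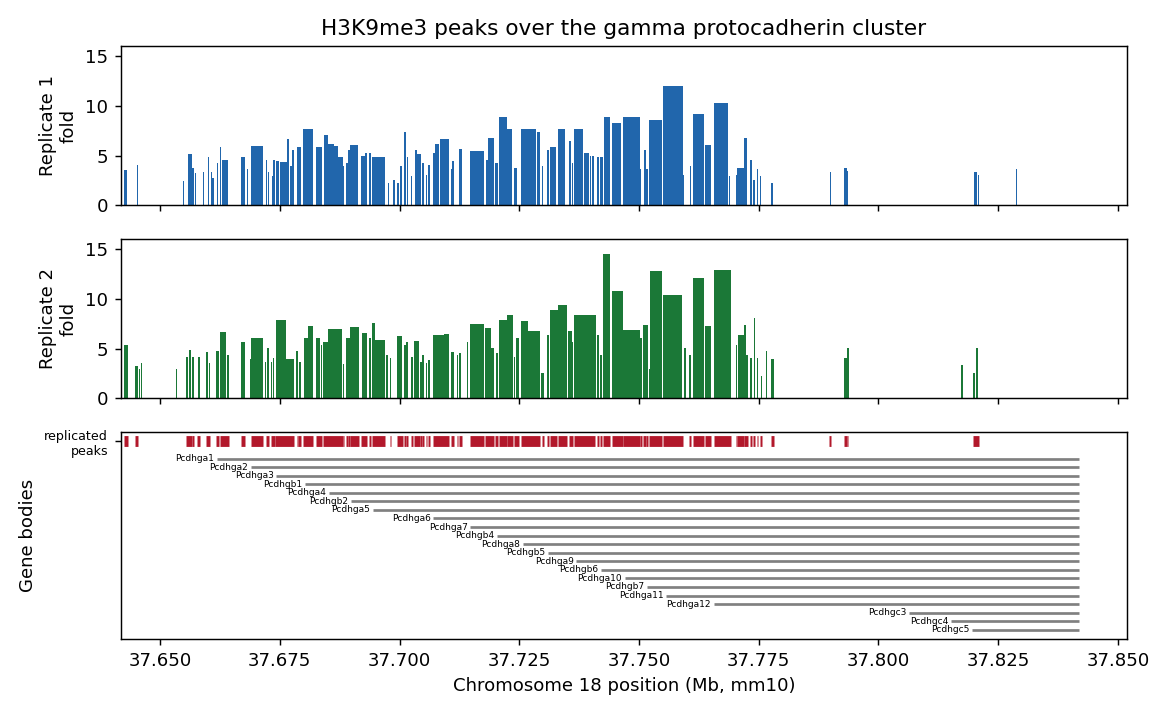
Peaks over the gamma protocadherin cluster on chromosome 18 (x axis, Mb, mm10), with bar height giving the authors' fold in replicate 1 (blue) and replicate 2 (green), and the replicated peaks (red) and gene bodies (grey) below. The folds reached 11.9 in replicate 1 and 14.4 in replicate 2, and the largest domain of replicated peaks ends at 37778133, upstream of the shared 3′ end of the genes at 37841873.

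Imprinted genes, expressed from the copy of one parent, held peaks in 39 of 47 protein-coding members (83.0%, against 31.8% by chance, adjusted permutation p = 0.00087). The replicate lists gave 87.2% and 85.1% (86.2% ± 1.5, SD, n = 2), against a chance share of 45.85% and 47.74% in these longer lists. Gnas, a complex locus that encodes the stimulatory G protein alpha subunit, had 12.2 kb covered and a highest fold of 7.91 (chromosome 2, 174284320 to 174346744, mm10). Grb10, a growth factor receptor adaptor, had 9.83 kb covered and a highest fold of 8.24 (chromosome 11, 11930508 to 12038683). Airn, the noncoding RNA antisense to Igf2r, had 9.09 kb covered and a highest fold of 6.87. A peak lay within 2 kb of the 5′ end in 16 of the 47 genes.

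Germline genes, active in germ cells and silent in other tissues, held peaks in 23 of 45 members (51.1%, against 27.0% by chance, adjusted permutation p = 0.0013). The replicate lists gave 64.4% and 57.8% (61.1% ± 4.71, SD, n = 2), against a chance share of 44.1% and 46.6% in these longer lists. Tdrd9, a helicase of the piRNA pathway, had 2.82 kb covered, with a highest fold of 5.96. Taf7l, a testis paralog of a general transcription factor, had 1.5 kb covered at a highest fold of 5.40, and Tdrd1 had 1.35 kb covered at 4.65. A promoter peak was present in 14 of the 45 genes. Without replicate 1 the share was 57.8% against 46.6% by chance (adjusted permutation p = 0.29).

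Zinc finger genes of the Zfp, Zkscan and Zscan symbols, many of them transcriptional repressors, held peaks in 175 of 424 members (41.3%, against 20.0% by chance, adjusted permutation p = 0.00087). The replicate lists gave 50.2% and 54.0% (52.1% ± 2.67, SD, n = 2), against a chance share of 31.84% and 34.15% in these longer lists. Zfp110 on chromosome 7 (12834761 to 12850577, mm10) had 83.9% of its body covered, Zfp873 on chromosome 10 had 79.1% and Zfp933 on chromosome 4 had 51.6%, with highest folds of 8.10, 10.6 and 8.56. Whether reads shared between paralogs add to these peaks was not tested. At promoters alone these genes held peaks in 7.31% (chance 5.16%, adjusted permutation p = 0.58).

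In zinc finger genes the mark lay over the last exon more often than over the promoter. A replicated peak overlapped the last exon in 127 of 424 genes (30.0%) and the promoter in 31 (7.31%), a difference of 22.6 percentage points. The last exon held a peak in 107 of 299 genes (35.8%) that had another gene of the Zfp, Zkscan and Zscan symbols within 500 kb. In the 125 others it did so in 20 (16%). This split was chosen after the data were seen, and the difference between its parts was not tested. Shifted peaks gave a difference of -1.08 points (permutation p = 0.0001, the smallest the shifts can give). The difference was 20.8 points in replicate 1 and 22.9 in replicate 2. The last exon alone was marked in 107 genes, the promoter alone in 11 and both in 20. Among the 21514 other protein-coding genes, 2.25% had a peak in the last exon and 3.35% in the promoter. The last exons had a median length of 2555.5 bp, shorter than the 4001 bp promoter window.

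The remaining 22 lists did not pass the threshold in either direction, with adjusted permutation p from 0.26 to 1. Among lists of kidney cell types, peaks lay in 2 of 18 nephron progenitor genes (11.1%, chance 22.5%), namely Cited1 and Robo2. The lists of replicates 1 and 2 held peaks in 27.8% and 33.3% of these (chance 33.0% and 35.0%). Replicated peaks lay in 7 of 17 podocyte genes (41.2%, chance 37.3%), with Magi2, Plce1 and Ptpro the most covered. Peaks also lay in 3 of 21 proximal tubule genes (14.3%, chance 23.6%), namely Slc27a2, Cdh6 and Slc13a3, and in 2 of 16 loop and distal tubule genes (12.5%, chance 22.3%), namely Trpm6 and Tfap2b. Of the ureteric epithelium genes 1 of 20 held a peak (5%, chance 15.8%), Wnt7b. The lists of replicates 1 and 2 gave 15% and 25% for these genes (chance 26.8% and 29.7%). Of the stromal genes 3 of 19 held a replicated peak (15.8%, chance 25.7%), namely Ntn1, Pdgfrb and Meis1. Endothelial genes gave 6 of 15 (40%, chance 31.1%), with Flt1, Pecam1 and Tek the most covered. Blood and immune genes gave 0 of 19 (chance 14.2%, permutation p = 0.059, adjusted 0.26). The lists of replicates 1 and 2 each held peaks in 15.8% of the blood and immune genes (chance 22.5% and 24.8%). Regulators and markers of other lineages gave 5 of 36 (13.9%, chance 11.5%), namely Rbfox3, Zfp42, Ckm, Nkx2-1 and Pdx1, of which the last pair was named after its values were seen. The peak of Zfp42, a pluripotency marker, had a fold of 7.07. Slc13a3 and Nkx2-1 held no peak in the list of replicate 1.

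Among clustered families, keratins gave 0 of 146 (chance 3.48%, permutation p = 0.053, adjusted 0.26), Hox genes 0 of 39 (chance 6.51%), olfactory receptors 51 of 1135 (4.49%, chance 6.89%) and vomeronasal receptors 65 of 329 (19.8%, chance 14.8%, adjusted permutation p = 0.33). Vmn2r60, on chromosome 7, was the most covered of these with 7.36 kb. Vomeronasal receptors passed the threshold only against gene lists matched on length (chance 11.1%, adjusted permutation p = 0.00052). Those lists draw genes independently and ignore tandem clusters, which the shifts keep, so this p is likely too small. Cytochrome P450 genes gave 20 of 77 (26.0%, chance 20.9%), and serpins 2 of 50 (4%, chance 13.5%), Serpina9 and Serpinb9c. Defensins gave 3 of 64 (4.69%, chance 3.38%), Defb33, Defb4 and Defb39. Trace amine and taste receptors gave 2 of 50 (4%, chance 1.52%), Tas2r130 and Tas2r107. Histones gave 2 of 68 (2.94%, chance 2.22%), Hist1h2aa and Hist1h2ba, and Rhox genes 1 of 34 (2.94%, chance 2.04%), Rhox13. Ribosomal protein genes gave 1 of 79 (1.27%, chance 4.99%), the testis paralog Rpl10l, and housekeeping genes 1 of 23 (4.35%, chance 10.9%), Tbp. Genes of the H3K9 methylation machinery gave 6 of 26 (23.1%, chance 28.8%), among them Atf7ip with 3.67 kb covered and Setdb1, an H3K9 methyltransferase, with 0.647 kb. Tas2r107, Defb39 and Hist1h2aa held no peak in the list of replicate 1, and Serpinb9c held none in that of replicate 2.

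**Figure D3:**
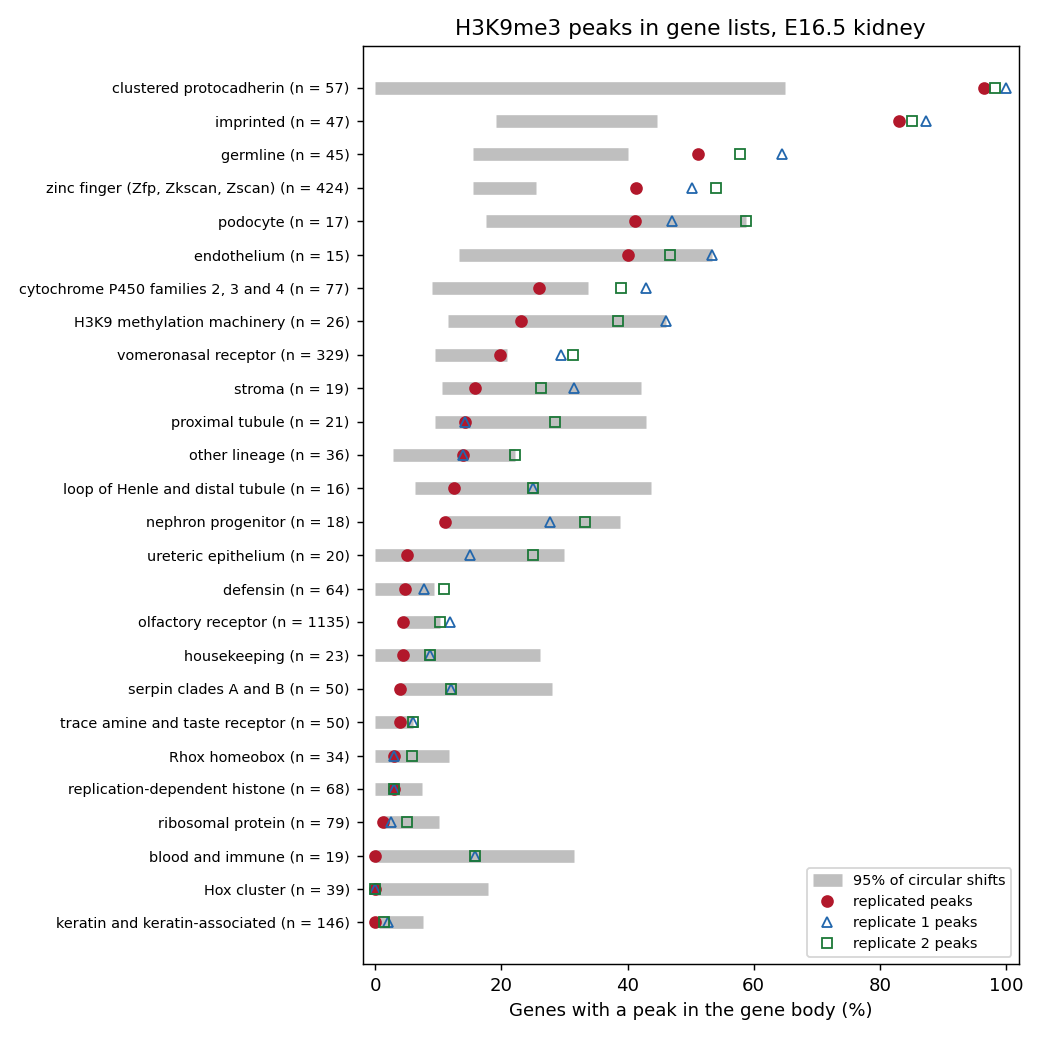
Percent of the genes of each list with a peak in the gene body (x axis), for replicated peaks (red circles) and the lists of replicate 1 (blue triangles) and replicate 2 (green squares). Grey bars span 95% of the circular shifts of the replicated peaks, and the 4 lists at the top lie to the right of them.

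Relative to genes, 63.6% of replicated peak midpoints were intergenic (chance 58.2%), 31.1% intronic (chance 37.1%) and 3.41% exonic (chance 2.55%), each with adjusted permutation p = 0.00013. Promoters held 1.86% (chance 2.21%, adjusted permutation p = 0.017). This promoter call was lost without replicate 2 (1.97%, chance 2.18%, adjusted permutation p = 0.064), above the median fold (0.11) and by any overlap (0.16). The replicate means were 65.0% ± 0.535 intergenic, 30.1% ± 0.855 intronic, 2.94% ± 0.207 exonic and 1.89% ± 0.113 in promoters (SD, n = 2). By any overlap instead of the midpoint, the exon share was 4.88% against 5.22% by chance (adjusted permutation p = 0.16).

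Peaks were richer in GC than shifted peaks, at 45.8% against 41.8%, held more CpG sites, at 0.979 against 0.849 per 100 bp, and were lower in soft-masked repeat bases, at 30.3% against 33.7% (permutation p = 0.001 for each, the smallest that 1000 shifts can give). The replicate lists gave 45.8% ± 0.532 GC and 29.2% ± 1.42 soft-masked bases (SD, n = 2). Shifts do not account for where reads can be mapped uniquely, so the lower share of repeat bases need not reflect where the mark lies.

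By chromosome, replicated peaks were densest on chromosomes 7 (22.2 per Mb) and 17 (19.6 per Mb), against a mean over autosomes of 12.3. Chromosome X had 3.58 peaks per Mb and chromosome Y 0.0681, from 6 replicated peaks. These densities do not account for where reads can be mapped uniquely. On X the replicates differed, with 9.07 peaks per Mb in replicate 1 and 19.3 in replicate 2, a ratio of 2.13. The same ratio ranged from 1.05 to 1.31 over the 19 autosomes. Both pools held embryos of both sexes, in shares not given in the sources used here. Without replicate 1 the X density was 0.695 times the autosome mean, and without replicate 2 it was 0.377 times. No test between chromosomes was made.

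**Figure D4:**
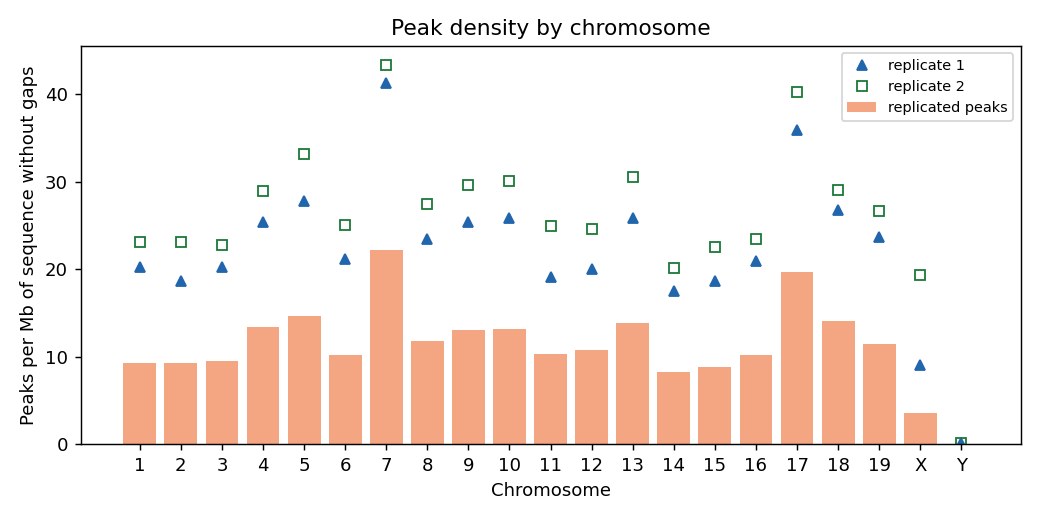
Peaks per Mb of sequence without gaps (y axis) by chromosome (x axis), as bars for replicated peaks, blue triangles for replicate 1 and green squares for replicate 2. On X the density was 9.07 in replicate 1 and 19.3 in replicate 2.

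Merged within 10 kb, replicated peaks formed 18814 domains, of which 14008 were single peaks. The 561 domains with 5 or more peaks held 22.7% of the covered bases. The domain with the most covered bases lay over the gamma protocadherins (chromosome 18, 37655512 to 37778133, mm10), with 90.4 kb covered by 72 peaks. The next was the Ugt1a cluster of glucuronosyltransferases (chromosome 1, 88203248 to 88256821), with 43.1 kb covered by 20 peaks, followed by the beta protocadherins with 37.0 kb. Zfp369 and Gm10775 on chromosome 13 (34.8 kb), Vmn1r66 (29.8 kb), Nlrp4e and Nlrp5 (27.2 kb), and Zscan18, Zfp329 and Zfp110 (26.0 kb), all but the first on chromosome 7, were also among the top 10. The other 3 domains held no protein-coding gene and lay on chromosomes 4 (32.0 kb), 7 (29.3 kb) and 3 (29.2 kb).

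The replicated peak of highest fold, 18.2, lay over Klf14 on chromosome 6 (30956937 to 30958919, mm10), a transcription factor gene in the imprinted region of Mest. Of its 1983 bp, 975 were coding and 1008 untranslated, and the fold was 14.7 in replicate 1 and 16.3 in replicate 2. Peaks over the variable exons of Pcdhga12 (fold 12.8, 68.2% coding) and Pcdhga11 (11.7, 60.1% coding) also ranked in the top 10. So did peaks in an intron of Trim24 (12.1) and of Mvb12b (11.6), a mainly intronic peak of Pkp4 (12.1, 9.85% coding), and a peak at Zfp981 (11.8, 16.4% coding). Peaks in the untranslated regions of Zfp606 and Zfp810 had a fold of 11.5 each, and a scaffold of chromosome 4 held 1 peak at 12.1.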

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

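The test by region was chosen after the result by peak was seen, because many of the peaks lie side by side.

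Scaffolds outside the assembled chromosomes, which the tests of the gene lists, compartments and replicate overlap left out, held 245 replicated peaks (0.818% of the list). No expected number was computed for them. They lay on 20 scaffolds, with a median fold of 3.88 and 62 of them on the unplaced scaffold JH584304. The lists of replicate 1 and replicate 2 held 350 and 356 peaks on scaffolds.

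The p-value column, which no comparison used, set apart 25 of the 50 replicated peaks with the smallest p, because their fold was under the 90th percentile of the list (4.95). The smallest p of all belonged to a peak at Drg1 on chromosome 11 (3198815 to 3200120, mm10), with −log10 p of 161.8 at a fold of 3.96. A technical explanation is that these peaks lie where the assembly is incomplete. Of the 25 peaks, 52.0% (13) were on scaffolds or within 50 kb of a gap, against 2.57% of the other replicated peaks (Fisher's exact test, two-sided, p = 9.2e-15), but these 13 lie in only 2 places, with 11 on the scaffold JH584304 and 2 side by side on chromosome 13, so by region it was 2 of 8 against 1.35% of 11302 (Fisher's exact test, two-sided, p = 0.0049). Incomplete assembly may account for these 2 places, while the rest, among them the peaks at Drg1 and Sfi1, stay open, and no biological explanation was tested.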

How the results depend on the processing

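All alternatives were planned except 4 chosen after seeing the data, namely −log10 q of 3 or more on X, isolated zinc finger genes, leaving out the protocadherin list, and gene families by symbol stem. Replicate overlap, zinc finger ends, GC and soft-masked shares kept their direction and their side of the threshold under every alternative run. With no counts in the files, what depth limits cannot be given. No paired analysis was possible because the labels give only 1 group.

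The 4 lists past the threshold became 2 to 3 in the replicate lists alone, with 2 without replicate 1. In the scan of 131 other symbol families 0 passed, which says nothing on these 4 lists, since families mostly within the lists were left out of it. Protocadherins lost the call in the pooled list (98.3%) and in the replicate lists (98.3% to 100%), germline genes without replicate 1 (57.8% to 64.4% in the replicate lists), and zinc finger genes at promoters alone (7.31%). The promoter share lost its call at 1.93% above the median fold, at 2.40% by any overlap, and without replicate 2 (1.81% to 1.97%). By any overlap the exon share turned to under chance (4.88%). For protocadherins the share by chance rose in these longer lists, to between 51.7% and 55.1%. The two-sided test then also counts shifts that leave every member without a peak. For the others the cause was not tested.

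Relative to the autosome mean, chromosome 7 (1.80) gave 1.56 to 1.71 in the replicate lists. Chromosome 17 (1.60) gave 1.45 to 1.49, 1.51 in the pooled list and 1.68 above the median fold. Chromosome X (0.291) gave 0.377 to 0.695, and Y (0.00554) gave 0.00367 to 0.00612, 0.0109 above the median fold and 0.0105 by bases. The X ratio of the replicates against autosomes (1.85) was 2.49 at −log10 q of 1.3 or more, 2.07 above the median fold and 1.85 at −log10 q of 3 or more. Domains (18814) numbered 31271 in the pooled list, 33755 to 36957 in the replicate lists and 10555 above the median fold. The largest (90.4 kb) covered 103 kb in the pooled list, 93.3 to 99.1 kb in the replicate lists and 139 kb at 25 kb merging. Longer lists give more domains and a wider merging distance gives larger ones by construction, and for the chromosomes the cause was not tested.

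Of 198 values of lists without a call, 162 stayed on the same side of chance without a call, though their sizes moved. Only 1 gained a call (vomeronasal receptors, 19.8%, against length-matched lists, which ignore tandem clusters). A further 35 moved to the other side of chance, with no adjusted permutation p under 0.53, and the cause was not tested. Those were, with 5 kb extensions, olfactory receptors (14.8%), Rhox (2.94%), defensins (9.38%), histones (4.41%), podocyte (41.2%) and other lineage (16.7%). With 500 bp covered they were taste receptors (0%), defensins (0%), histones (0%), podocyte (23.5%) and H3K9 machinery (15.4%). In the pooled list they were Rhox (2.94%), histones (2.94%), endothelium (40%) and other lineage (16.7%). Above the median fold they were defensins (1.56%), P450 (10.4%), histones (0%), endothelium (13.3%), other lineage (2.78%) and H3K9 machinery (23.1%). At promoters alone they were histones (2.94%), nephron progenitor (5.56%), podocyte (0%), endothelium (0%) and H3K9 machinery (11.5%). Against length-matched lists they were Rhox (2.94%) and histones (2.94%). In both replicate lists they were Rhox (2.94% to 5.88%) and histones (2.94% to 2.94%). Podocyte (47.1% to 58.8% in the replicate lists) and other lineage (13.9% to 22.2%) crossed only without replicate 2, at the lower value, and endothelium (46.7% to 53.3%) only without replicate 1, at the lower value.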

Other observations

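The tests of symbol families, of isolated zinc finger genes, of X peaks at −log10 q of 3 or more, of X peaks matched from the replicated list and from replicate 2, and of tRNAs with few sites were chosen after earlier results were seen.

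Reverse transcription of retroviruses starts from a host tRNA, which pairs with an 18-base site in the viral genome. Genome copies of such sites outside tRNA genes lay near replicated peaks more often than shifted peaks did for 9 of 12 tRNAs (adjusted permutation p under the threshold). Of 1090 sites for phenylalanine tRNA, 254 (23.3%) had a peak within 1 kb, against 2.40% by chance, and 26.5% and 34.9% did in the lists of replicates 1 and 2. Sites for proline tRNA gave 56 of 174 (32.2%, chance 1.91%), lysine 46 of 176 (26.1%, chance 2.40%), threonine 20 of 47 (42.6%, chance 2.46%), isoleucine 64 of 652 (9.82%, chance 2.42%), glutamine 21 of 154 (13.6%, chance 2.45%) and glycine 18 of 308 (5.84%, chance 2.06%). Methionine and asparagine tRNAs passed with 8 of 16 and 2 of 3 sites. The result is consistent with H3K9me3 at endogenous retroviruses, as a hypothesis, since sites were matched by sequence alone and soft-masked bases as a whole were less frequent in peaks than by chance.

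Outside the gene lists, 131 families were defined by symbol stem, leaving out those mostly within the lists, such as the zinc finger and protocadherin genes. Of these 131, 0 passed the adjusted threshold in the shift test, with 12 at an unadjusted permutation p under 0.05. The smallest p was for Kdm genes, demethylases among others, with peaks in 0 of 18 (chance 33.4%, adjusted permutation p = 0.079). Secretoglobins gave 9 of 34 (26.5%, chance 4.41%, adjusted permutation p = 0.12).

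Zinc finger genes held peaks in 41.3% of members, and gene length, base composition or tandem clusters could account for that. Random lists held peaks in 16.7% on average when matched on length and in 17.5% when matched on length and GC. The upper bounds of their 95% ranges were 20.1% and 20.8%, likely too low, since random lists ignore tandem clusters. The distance of both means from 41.3% still argues against length and GC as the whole cause. The 125 zinc finger genes with no other of these symbols within 500 kb held peaks in 34.4% (chance 26.5%, permutation p = 0.028). The 299 others held peaks in 44.2% (chance 17.4%), a larger excess. The excess in the 125 genes argues only weakly against clusters of the Zfp, Zkscan and Zscan symbols as the whole cause. Its p was not adjusted, and the test was run on replicated peaks only. Zinc finger genes under other symbols were not counted as neighbours, so clusters that include them stay open. Reads shared between paralogs were not tested and stay open.

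On chromosome X, replicate 2 held 3161 peaks and replicate 1 held 1483. A few regions are argued against, since the 10 percent of bins of 5 Mb with the largest excess held 26.6% of the extra peaks and 32 of 34 bins showed an excess. Weak peaks near the calling threshold are argued against as the whole cause. At −log10 q of 3 or more the ratio of relative densities was still 1.85 (352 against 86 peaks). A stricter cutoff is itself a threshold, so a difference in depth between the replicates, which is unknown, is not excluded. Higher X signal throughout replicate 2 stays open. The median log2 fold ratio of shared peaks, X minus autosomes, was 0.11 (95% bootstrap interval -0.01 to 0.13) matched from the replicated list. It was 0.102 (-1.57e-06 to 0.14) from replicate 2 and 0.08 (0.02 to 0.10) from replicate 1, the first matching run. The X median was above that of every autosome in all 3 matchings (0.26 against at most 0.22, 0.23 against 0.19 and 0.27 against 0.24). The size set for this explanation, a difference over 0.1 with its interval above 0, was met in none. The matching from replicate 2 missed it only by a lower bound just under 0, and only the matching from replicate 1 lay wholly under 0.1. The share of male and female embryos in each pool, a biological difference that may matter, is not given in the sources used here and was not tested.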
